A study of Mus musculus with 32 samples.

How the data were processed

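Single mouse embryos at the late 2-cell stage, 28 h after in vitro fertilization, were profiled by mRNA sequencing. Per the labels and the series' design text, wild-type embryos had been microinjected with mRNA for a fusion of histone H3.3 and green fluorescent protein together with an oligonucleotide containing locked nucleic acid (LNA). In 16 embryos, called Val_LNA, the oligonucleotide was antisense to tRFValCAC, a fragment of a valine transfer RNA. In the other 16 embryos, called Ctrl_LNA, it was a scrambled sequence. Embryos positive for the fluorescent protein were kept for sequencing, per the design text. Each library is 1 embryo, and nothing in the labels says whether the embryos of a group came from separate matings or injection days, so p-values measure the spread between these embryos.

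Per the labels' protocols, each embryo was lysed in its own well, RNA was bound to beads, polyadenylated RNA was reverse transcribed with template switching, the cDNA was amplified by 20 PCR cycles, and libraries were made by tagmentation. No molecular identifiers are named, so PCR copies count as separate reads, and any interval from counts would cover counting error only. The protocol does not mark the strand of the RNA, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, Bowtie2, STAR, SAMtools and DESeq2 were used with the mouse build mm10. Their versions, their roles and the gene annotation are not given in the sources used here.

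The deposited table holds a signal per gene and embryo, which the authors made by dividing gene counts by DESeq size factors, per the file names and the file headers, for 34223 genes. A second deposited file holds the size factors. Multiplying each value by the size factor of its embryo gave a whole number of reads for 1095136 of 1095136 values (100%), within the rounding of the deposited decimals, with a largest distance of 0.0086 from a whole number. These recovered reads gave the depth of each embryo and entered the count tests. No column was without a sample. Identifiers matched GENCODE M21, an annotation of the same mouse assembly (GRCm38), for 34179 of 34223 genes (99.9%) when version numbers were ignored, and coordinates are from that annotation, counted from 1. No pair of libraries looked like 1 library deposited more than once: over the 240 pairs within a group, the lowest chi-square per gene was 25.3.

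The main test was limma (version 3.58.1, in R 4.3.3) with trend and robust options on log2(normalized count + 1), over the 15559 genes with a normalized count of at least 10 in at least 8 of the 32 embryos. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A log2 fold change is the difference of the group means of log2(normalized count + 1), Val_LNA minus Ctrl_LNA. It understates the change of low genes, and where a gene is near 0 in some embryos it can exceed the log2 ratio of the mean counts. The design, 23 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 highest and the 10 lowest log2 fold changes among called genes with a mean normalized count of at least 50 and a symbol that is not a Gm, Rik or LOC model name. It also took the 5 genes with the smallest p, up to 4 called members of each list with the smallest p or the 1 member with the smallest p where none was called, and H3f3a, H3f3b and Hnrnpab. It gave 65 genes, of which 56 were called. The values of a single gene among these are not reported here, and those of the others are.

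Lists were tested with camera at its preset correlation of 0.01, adjusted over the 23 lists. Camera compares a list with all other tested genes. Camera with an estimated correlation and fry were run beside it. Fry's directional p tests whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares a list with other genes. Scores per embryo are the mean over tested list members of log2(normalized count + 1), each gene centred on its mean over the 32 embryos. Differences of scores, reads, genes detected, mitochondrial shares and shares of the 10 highest genes were tested by two-sided permutation tests with 100000 resamples, or by exact permutation tests where a group had fewer than 10 embryos (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Figures were drawn with matplotlib 3.10.9.

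Alternatives were edgeR's quasi-likelihood test (version 4.0.16), DESeq2 (version 1.42.0) and limma-voom on the recovered reads, a Wilcoxon rank sum test, other pseudocounts, filters, scalings and covariates, array weights, each run of library numbers alone, and leaving out each embryo. Library numbers are the numbers in the labels. They form 4 unbroken runs of 8 embryos, 1 to 8 and 13 to 20 in Val_LNA and 31 to 38 and 43 to 50 in Ctrl_LNA, which the labels do not call batches. Leaving out embryos with under 50% of the median depth removed 0 embryos and so changed nothing. Settings without Ctrl_LNA 48 under edgeR, DESeq2, limma and the score tests, the covariate taken from the control embryos, and the relations between scores, were chosen after seeing the data.

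The tests were tried on simulated data for the comparison of 16 with 16 embryos, with counts drawn from the real means, dispersions and library sizes and 200 changed genes, 14647 genes passing the filter. Recovered shares are of the changed genes that passed the filter, so changed genes lost to the filter are not counted as missed. At a fold of 2, limma recovered 10.6% of these genes, edgeR 9.6% and DESeq2 23.4%. At a fold of 4 the shares were 53.7%, 52.6% and 68.4%. Of the calls, 5 of 66 in limma, 2 of 61 in edgeR and 20 of 107 in DESeq2 were false. All true calls had the right sign. Genes were drawn independently, so the simulation holds no variation shared between genes and no embryo that lacks many transcripts. Its shares may therefore differ from those in the real data.

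For the named genes, exons overlapping another tested gene and transcripts of other genes with at least 95% identity over at least 200 bases were looked up in the annotation. A copy also had to align over a large part of the named gene's longest transcript. Shorter near-identical stretches were not listed, so genes without a listed copy may still share them. Of the 65, 19 had such an overlap or copy, and their values are uncertain to that extent. Overlaps were found for Pcyt1a, 2810403A07Rik, Tm2d3, Sardh, Arg2, Tsr1, Nop56, Srrm2, Atp5d, mt-Co1, Cyp51, Eif5b, Ago2, Hnrnpab and H3f3a, and copies for Hnrnpa1, Hspb1, Eif3h, Ythdf2 and mt-Co1.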

Results

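The data were normalised read counts for 34223 genes in 32 single mouse embryos at the late 2-cell stage, collected 28 h after in vitro fertilization. At this stage the embryo replaces RNA stored in the egg with RNA made from its own genome. All embryos carried an injected message for histone H3.3 fused to green fluorescent protein, 16 with an antisense oligonucleotide against tRFValCAC (Val_LNA) and 16 with a scrambled oligonucleotide (Ctrl_LNA). The comparison asks which transcripts differ when this valine tRNA fragment, which the series title calls enriched in sperm, is inhibited.

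The recovered totals lay between 2592925 and 6259870 reads per embryo, with 4392531 ± 947194 in Val_LNA and 4837221 ± 686052 in Ctrl_LNA (SD, n = 16 each). The difference of the mean log2 totals was -0.16 (two-sided permutation test, p = 0.114), with -0.27 in the lower runs of library numbers, 1 to 8 against 31 to 38 (exact permutation p = 0.0937, n = 8 and 8) and -0.05 in the upper runs, 13 to 20 against 43 to 50 (exact permutation p = 0.684, n = 8 and 8). A value above 0 was found for 18186 ± 831 genes in Val_LNA and 17782 ± 2962 genes in Ctrl_LNA (SD, n = 16 each, permutation p = 0.816), and without Ctrl_LNA 48 the difference was -296 (permutation p = 0.373). The wide spread of the control group came from 1 embryo, Ctrl_LNA 48, in which 7276 genes were detected from 5122089 reads, against 16687 to 20200 genes in the other 31 embryos. Its median correlation with the other embryos over the tested genes was 0.496, against at least 0.609 for every other embryo. Mitochondrially encoded genes took 3.52% ± 0.696 of the normalised counts in Val_LNA and 3.15% ± 0.462 in Ctrl_LNA (SD, n = 16 each, permutation p = 0.083). In the lower runs the difference was 0.526 percentage points (exact permutation p = 0.104, n = 8 and 8), and in the upper runs 0.219 (exact permutation p = 0.39, n = 8 and 8). The 10 highest genes of an embryo, a measure tested after its values were seen, took 5.64% ± 1.08 of the counts in Val_LNA and 4.86% ± 0.753 in Ctrl_LNA (SD, n = 16 each, permutation p = 0.0244), and 4.80% ± 0.732 without Ctrl_LNA 48 (permutation p = 0.0179). In the lower runs that difference was 0.876 percentage points (exact permutation p = 0.088, n = 8 and 8), and in the upper runs 0.677 (exact permutation p = 0.155, n = 8 and 8).

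Pcyt1a, Mcm6, Srsf10 and Hnrnpa1 were among the transcripts that fell in Val_LNA embryos. Pcyt1a, which encodes the enzyme that controls phosphatidylcholine synthesis, fell from 1125 ± 285 to 238 ± 150 normalised counts (SD, n = 16 each), and Mcm6, a subunit of the replicative helicase, from 1397 ± 351 to 216 ± 228. Srsf10, a regulator of splicing, fell from 1514 ± 624 to 564 ± 170, and Hnrnpa1, an RNA-binding protein of splicing and RNA export, from 2389 ± 1487 to 768 ± 331. Among the transcripts that rose were Prl8a2, a hormone of the prolactin family, from 5.11 ± 11.9 to 149 ± 136, and Mki67, a protein of dividing cells, from 329 ± 295 to 810 ± 236. In all, 137 genes were higher and 204 lower in Val_LNA embryos at an adjusted p under 0.05 in limma, of 15559 tested.

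The counts of calls moved with the test and with Ctrl_LNA 48. Without that embryo limma called 245 genes higher and 409 lower, 137 and 204 of them shared with the calls from all embryos. EdgeR called 29 genes higher and 163 lower, and 28 and 129 of these were among the limma calls. With Ctrl_LNA 48 also left out, edgeR called 84 higher and 250 lower, and DESeq2 266 higher and 402 lower. The median log2 fold change of all tested genes was 0.26 with 32 embryos and 0.07 without Ctrl_LNA 48. With each embryo centred on its median gene that median was -0.19, and 61 genes were called higher and 300 lower, so the share of higher calls was 16.9% in place of 40.2%.

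The runs of library numbers gave pairs of groups with no embryo in common. Between Val_LNA 1 to 8 and Ctrl_LNA 31 to 38, limma called 97 genes higher and 83 lower. Between Val_LNA 13 to 20 and Ctrl_LNA 43 to 50, it called 2 higher and 33 lower, and 7 higher and 124 lower without Ctrl_LNA 48. Of the 180 genes called in the lower runs, 165 (91.7%) had the same sign in the upper runs, 76 with an unadjusted p under 0.05, and 14 were called in both. Of all tested genes 59.5% had the same sign in both. The test of a difference between these effects called 0 genes in limma, with 808 at an unadjusted p under 0.05. Between the runs within a group, limma called 0 genes in Val_LNA (913 at an unadjusted p under 0.05) and 0 genes in Ctrl_LNA (1422, or 1682 without Ctrl_LNA 48).

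The 5 genes with the smallest p were Pcyt1a, 2810403A07Rik, Mcm6, Tigd3 and Prl8a2, each with an adjusted p of 1.53e-06. Pcyt1a (ENSMUSG00000005615.15, chromosome 16, 32430921 to 32475070) had a log2 fold change of -2.49 ± 0.29 (SE), and 16 of 16 Val_LNA embryos lay below the control median. Mcm6 (ENSMUSG00000026355.11, chromosome 1, 128331590 to 128359664) had a log2 fold change of -3.38 ± 0.40, with 16 of 16 embryos below that median. For 2810403A07Rik (ENSMUSG00000028060.14, chromosome 3, 88685803 to 88712924) the log2 fold change was -2.30 ± 0.27, with 245 ± 145 normalised counts in Val_LNA and 1176 ± 745 in Ctrl_LNA. Tigd3 (ENSMUSG00000044390.4, chromosome 19, 5891138 to 5894149), a gene derived from a transposase, was detected in 2 of 16 Val_LNA and 15 of 16 Ctrl_LNA embryos. Prl8a2 (ENSMUSG00000018259.13, chromosome 13, 27345673 to 27354216) was detected in 16 of 16 Val_LNA and 6 of 16 Ctrl_LNA embryos, with a log2 fold change of 5.37 ± 0.63. All are protein-coding genes, with positions on GRCm38.

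**Figure D1:**
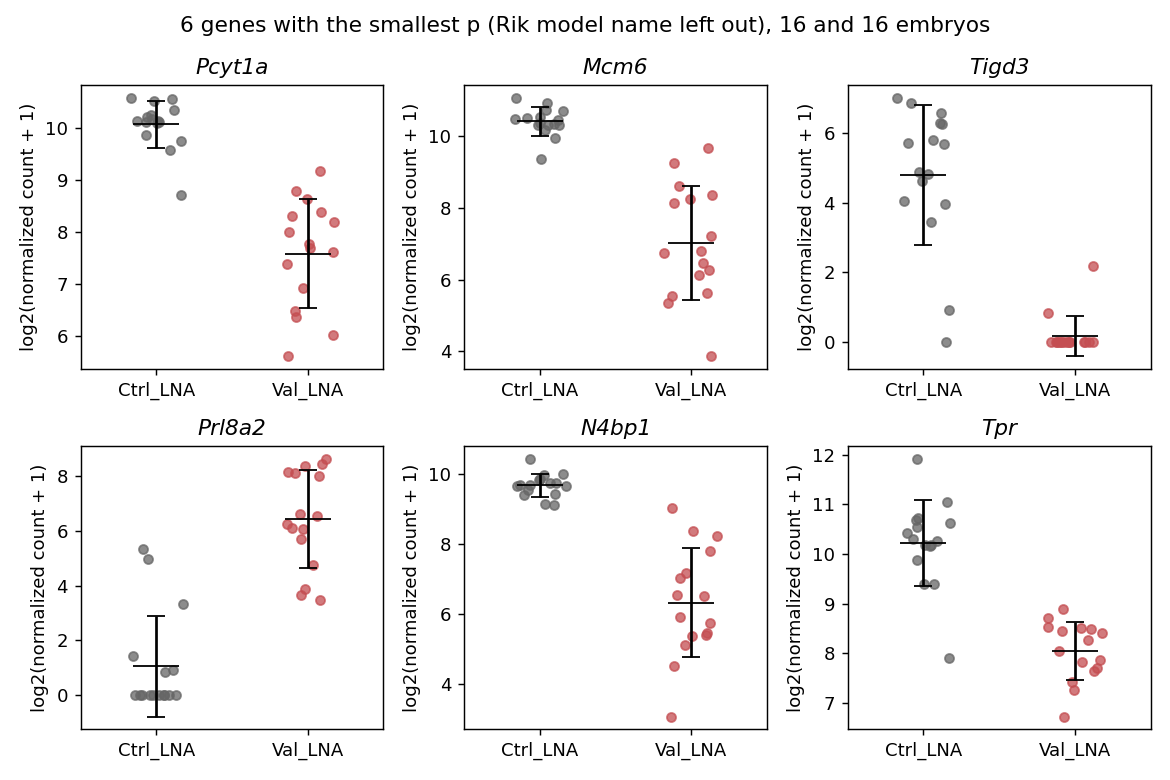
Each point is 1 embryo, with the log2(normalized count + 1) of a gene on the vertical axis and the group on the horizontal axis; bars give the mean and SD of 16 embryos, and N4bp1 and Tpr, next by p, were chosen after their values were seen. Tigd3 was detected in 2 Val_LNA and 15 Ctrl_LNA embryos, and Prl8a2 in 16 Val_LNA and 6 Ctrl_LNA embryos.

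Several of the largest decreases were transcripts detected in fewer Val_LNA than Ctrl_LNA embryos. Cmtr2, a methyltransferase of the mRNA cap, had the lowest log2 fold change among called genes with a mean of at least 50, at -4.57 ± 0.66 (SE, adjusted p = 3.9e-05) and was detected in 8 of 16 Val_LNA and 16 of 16 Ctrl_LNA embryos. The SUMO ligase gene Pias3 (-3.95), the RNA helicase gene Dhx37 (-3.94) and the primase subunit gene Prim2 (-3.64) were below the control median in 16 of 16 Val_LNA embryos. Sardh (-3.56), Ampd2 (-3.49), the noncoding RP24-353A8.2 (-3.45), Wdr45b (-3.44) and the histone demethylase gene Kdm3b (-3.43) followed. Tm2d3 fell from 1214 ± 629 to 136 ± 160 normalised counts (SD, n = 16 each), a log2 fold change of -3.40.

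The largest increases were mostly transcripts with low or uneven values in the controls. Tacr3, the receptor for neurokinin B, rose by 4.88 ± 0.71 on the log2 scale (SE, adjusted p = 3.9e-05), from 25.5 ± 37.2 to 291 ± 177 normalised counts (SD, n = 16 each). The RNA-binding protein gene Rbmx (3.99), Cttnbp2 (3.83), the histone demethylase gene Kdm4a (3.71), Msantd2 (3.34), RP23-40G2.3 (3.31), Hibadh (3.26), Ranbp3 (3.25) and Nxpe4 (3.21) followed. Of the 10 highest, only Prl8a2 and Tacr3 also passed in edgeR, where the adjusted p of the other 8 lay between 0.0608 (Nxpe4) and 0.425 (Msantd2) and the log2 fold change between 1.39 (Ranbp3) and 2.85 (Cttnbp2). In edgeR Tacr3 had a log2 fold change of 3.39, Prl8a2 4.54, Pias3 -2.59, Sardh -2.34, Wdr45b -2.13 and Mki67 1.17. Across all 56 called named genes, 36 also passed in edgeR and 50 in DESeq2. Besides those 8, the genes not called in edgeR were Pias3, Sardh, RP24-353A8.2, Wdr45b, Nop56, Hnrnpc, Atp5d, Cyp51, Mki67, Chd1, Eif4g1 and Eif3h. Those not called in DESeq2 were Rbmx, Msantd2, Ranbp3, Sardh, Eif4g1 and Eif3h.

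By number, in limma with all embryos, the spliceosome and SR protein list held the most called genes of the fixed lists. It was also one of the longest, and by share of members called the hnRNP list (below) lay slightly above it. Without Ctrl_LNA 48 it had 10 genes lower, against 9 lower and 1 higher in the ribosome biogenesis list. Of 78 tested members of the spliceosome and SR protein list, 7 fell, 0 rose and 71 did not pass, or 11 and 0 when adjusted over the list alone. Of all 15559 tested genes, 204 fell and 137 rose. Srsf10 (-1.42 ± 0.18, SE), Srrm1 (-1.10 ± 0.23), Tra2b (-1.37 ± 0.30) and Srrm2 (-1.55 ± 0.35) were below the control median in 16 of 16 Val_LNA embryos. The list was lower than other genes in camera (median -0.15, adjusted p = 1.36e-05), with adjusted p = 0.375 with an estimated correlation. Without Ctrl_LNA 48 the median was -0.28. Of 32 hnRNP genes, which package new transcripts, Hnrnpa1 (-1.57) and Hnrnpc (-0.57) fell and Rbmx rose, or 2 and 2 when adjusted over the list alone, where Hnrnpa2b1, chosen after its values were seen, was added. The hnRNP list was not called in camera (median -0.02, adjusted p = 0.161), but was called downwards from the edgeR statistics (median -0.18, adjusted p = 0.0196) and the DESeq2 statistics (median -0.10, adjusted p = 0.0306). Without Ctrl_LNA 48 these adjusted p were 0.0678 and 0.0586. In camera with an estimated correlation the list had adjusted p = 0.444 with all embryos and 0.612 without Ctrl_LNA 48. Hnrnpab had a log2 fold change of -0.42 ± 0.30 (adjusted p = 0.503).

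The list of genes that build ribosomes was lower than other genes in camera (median -0.29, adjusted p = 4.52e-08), with adjusted p = 0.375 with an estimated correlation. Of 71 ribosome biogenesis genes, 4 fell, 0 rose and 67 did not pass, or 8 fell and Nop14, chosen after its values were seen, rose when adjusted over the list alone. Those that fell were Wdr43 (-1.22 ± 0.23, SE), Tsr1 (-1.80 ± 0.35), Ftsj3 (-2.09 ± 0.46) and Nop56 (-0.93 ± 0.22). Of 79 cytoplasmic ribosomal protein genes, 64 had a negative log2 fold change. Their median was -0.29 (camera adjusted p = 2.4e-10, and adjusted p = 0.375 with an estimated correlation). Among translation factors, Eif5b (-1.03) and Etf1 (-0.67) fell and Eif4g1 (1.38) and Eif3h (2.53) rose, of 49, or 3 and 3 when adjusted over the list alone, with Eif3j1 and Eif4b, chosen after their values were seen. Both increases were called in neither count test, with an adjusted p of 0.416 for Eif4g1 and 0.642 for Eif3h in edgeR, where the log2 fold change of Eif3h was 0.86. The translation factor list had a median of -0.11 (-0.17 without Ctrl_LNA 48), a mean of 0.008 and a camera call downwards (adjusted p = 0.0161, and adjusted p = 0.375 with an estimated correlation). Of 33 proteasome genes Psmd11 fell (-1.32), also the count when adjusted over the list alone, and the list median was -0.25 (camera adjusted p = 0.000139, and adjusted p = 0.375 with an estimated correlation). Between the lower runs of library numbers the ribosomal protein and proteasome medians were -0.015 and -0.01, and neither list passed in camera (adjusted p = 0.491 and 0.84).

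Cell cycle genes changed in both directions. Of 48 DNA replication genes, Mcm6, Prim2 and the cyclin gene Ccne1 (-1.28 ± 0.31, SE) fell, 0 rose and 45 did not pass, or 4 fell and 1 rose when adjusted over the list alone, with Mcm10 and Pold3, chosen after their values were seen. The list had a median of 0.10 (-0.11 without Ctrl_LNA 48), a mean of -0.12 and a camera call downwards (adjusted p = 0.0454, and adjusted p = 0.444 with an estimated correlation). Of 42 genes of G2 and mitosis, Cks1b (1.05 ± 0.22) and Mki67 (1.93 ± 0.42) rose and 40 did not pass, or 2 rose and 5 fell when adjusted over the list alone, the latter Ttk, Kif20b, Prc1, Hmmr and Mad2l1, chosen after their values were seen. The list median was -0.10 and its mean 0.012 (camera adjusted p = 0.0454 downwards, adjusted p = 0.375 with an estimated correlation), and without Ctrl_LNA 48 the camera adjusted p was 0.487. Hist1h2bc, a replication-dependent histone gene, rose by 3.91 ± 0.66 and 14 of 15 tested histone genes did not pass, while 2 rose when adjusted over the list alone, with Hist1h4i, chosen after its values were seen. The histone list median was 0.86 (camera adjusted p = 0.00752 upwards, and adjusted p = 0.444 with an estimated correlation), but 0.42 with array weights (adjusted p = 0.0919) and 0.38 in the lower runs (adjusted p = 0.0443). With the control axis as a covariate and without Ctrl_LNA 48 it was 0.48 (adjusted p = 0.0686). Only 15 of the 45 listed histone genes in the data were tested. The libraries were made from polyadenylated RNA, so histone transcripts that are not polyadenylated are not covered by these values.

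Regulators of chromatin and of mRNA decay contained called genes, while neither list was called in camera. Of 71 chromatin genes, the arginine methyltransferase gene Prmt1 (-3.03 ± 0.45, SE), the histone chaperone gene Asf1b (-2.52 ± 0.47) and the remodeller gene Chd1 (-1.43 ± 0.37) fell and Kdm4a rose, or 4 and 2 when adjusted over the list alone, with Kdm6b and Arid1a, chosen after their values were seen. The list median was 0.12, and 0.023 without Ctrl_LNA 48, and camera gave an adjusted p of 0.233. Of 65 mRNA decay genes, Ythdf2, a reader of methylated mRNA (-1.54 ± 0.26), Ago2, the endonuclease bound by small RNAs (-1.51 ± 0.31), and Upf3b of nonsense-mediated decay (-0.97 ± 0.27) fell, 0 rose, and the same 3 fell when adjusted over the list alone. That list had a median of 0.23 (0.003 without Ctrl_LNA 48), a mean of 0.14 and camera direction downwards (adjusted p = 0.948). Of 34 genes of the p53 response, Aen, an apoptosis-linked exonuclease, fell from 445 ± 265 to 85.2 ± 44.3 normalised counts (SD, n = 16 each), also the count when adjusted over the list alone (camera adjusted p = 0.142). Of 34 heat shock and stress genes Hspb1 fell (-1.96), also when adjusted over the list alone (camera adjusted p = 0.333).

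Metabolic and mitochondrial lists held few calls. Slc16a1, a lactate transporter, fell (-1.07 ± 0.26, SE) among 21 glycolysis genes, joined by Aldoc, chosen after its values were seen, when adjusted over the list alone. The glycolysis median was -0.01, and -0.21 without Ctrl_LNA 48 (camera adjusted p = 0.0454 downwards, and adjusted p = 0.444 with an estimated correlation). Cyp51 rose (1.91 ± 0.48) among 23 cholesterol synthesis genes, and 3 others (Dhcr7, Mvk and Hmgcs1, chosen after their values were seen) fell when adjusted over the list alone (median 0.05, and -0.27 without Ctrl_LNA 48, camera adjusted p = 0.161 downwards). With array weights the camera adjusted p of that list was 0.0426, and with all embryos weighted alike adjusted p = 0.637 with an estimated correlation. With the control axis as a covariate and without Ctrl_LNA 48 its median was -0.24. The camera adjusted p was then 0.0326 downwards, and 0.159 with an estimated correlation. Atp5d fell (-1.37 ± 0.35) among 75 nuclear-encoded oxidative phosphorylation genes, also the count when adjusted over the list alone (median 0.24, and 0.023 without Ctrl_LNA 48, camera adjusted p = 0.948). Of 12 mitochondrially encoded transcripts 0 passed in limma, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, 0 called in edgeR or DESeq2), and mt-Co1 had 31082 ± 7188 normalised counts in Val_LNA and 24627 ± 5188 in Ctrl_LNA (SD, n = 16 each, adjusted p = 0.124). Their median was 0.20 with a camera call upwards (adjusted p = 0.0161, and adjusted p = 0.53 with an estimated correlation), and -0.25 with each embryo centred on its median gene, which lowers every list alike.

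The lists of 2-cell zygotic transcripts and of stored maternal transcripts were both called higher in Val_LNA embryos in camera, with adjusted p = 0.444 and 0.534 with an estimated correlation. With all 32 embryos no member of either rose past the threshold in limma, and without Ctrl_LNA 48 the maternal Fbxw24, chosen after its values were seen, did (0.53, adjusted p = 0.047). Of 27 tested 2-cell zygotic genes, 0 passed in limma, over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05, 0 called in edgeR, 4 higher in DESeq2), and 26 had a positive log2 fold change. The 4 in DESeq2 were Zscan4a, Zscan4c, Zscan4e and Zscan4f, chosen after their values were seen, which belong to a family of closely similar genes and are uncertain to that extent. Arg2 had the smallest p (1.36 ± 0.45, SE, adjusted p = 0.118). The list median was 0.80 with 32 embryos and 0.57 without Ctrl_LNA 48 (camera adjusted p = 0.00148 and 0.00225), and from edgeR statistics without that embryo it was 0.24 (adjusted p = 0.0613). In limma the median of all tested genes was also above 0, at 0.26 with 32 embryos and 0.07 without Ctrl_LNA 48. Of 46 maternal oocyte genes, Omt2b, an oocyte transcript, fell from 8616 ± 2590 to 5186 ± 2625 normalised counts (SD, n = 16 each), 0 rose, and the counts were equal when adjusted over the list alone. The maternal list median was 0.67, and 0.44 without Ctrl_LNA 48 (camera adjusted p = 0.00365 and 0.000655), but 0.12 in the lower runs (adjusted p = 0.491).

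The 2-cell zygotic score was 0.36 ± 0.59 in Val_LNA and -0.36 ± 1.16 in Ctrl_LNA (SD, n = 16 each), a difference of 0.71 (two-sided permutation test, p = 0.0282). Without Ctrl_LNA 48 the difference was 0.50 (p = 0.057), without Val_LNA 2 it was 0.64 (p = 0.0505) and without Val_LNA 8 it was 0.63 (p = 0.0533), so 3 single embryos each decided the call. Within the lower runs the difference was 0.38 (exact permutation p = 0.342, n = 8 and 8) and within the upper runs 1.05 (exact permutation p = 0.0123, n = 8 and 8), or 0.66 without Ctrl_LNA 48 (exact permutation p = 0.02, n = 8 and 7). The maternal score differed by 0.56 (p = 0.0759), by 0.08 within the lower runs (exact permutation p = 0.79) and by 1.05 within the upper runs (exact permutation p = 0.042), or 0.63 without Ctrl_LNA 48 (exact permutation p = 0.0883). The zygotic minus maternal index was 0.08 ± 0.55 in Val_LNA and -0.08 ± 0.58 in Ctrl_LNA, a difference of 0.15 that did not exceed the spread between embryos (p = 0.46), with 0.31 within the lower runs (exact permutation p = 0.321) and -0.0042 within the upper runs (exact permutation p = 0.987).

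**Figure D2:**
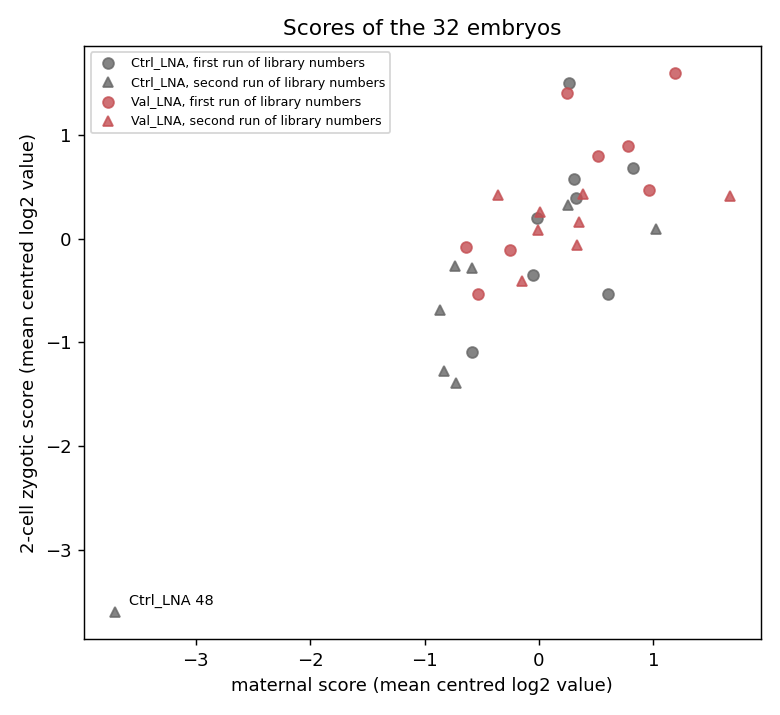
Each point is 1 embryo, with its maternal score on the horizontal and its 2-cell zygotic score on the vertical axis, both in centred log2 units; colour gives the group and shape the run of library numbers. Ctrl_LNA 48 lies at -3.71 and -3.60, apart from the other 31 embryos.

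The remaining lists held no gene called in limma, while among pluripotency genes DESeq2 called Yap1 higher and Dppa2 and Dppa5a lower, named after their values were seen. Zfp42, an embryonic stem cell factor, had the smallest p of 29 pluripotency genes (-3.14 ± 0.91, SE, adjusted p = 0.0584), with an adjusted p of 0.00474 without Ctrl_LNA 48. In edgeR its log2 fold change was -1.51 (adjusted p = 0.458), and its adjusted p in DESeq2 was 0.235. Adjusted over the list alone, Zfp42 and Dppa5a fell and Yap1 rose, the latter 2 chosen after their values were seen, and the camera call downwards (adjusted p = 0.0454, adjusted p = 0.375 with an estimated correlation) was at 0.107 without Ctrl_LNA 48. Of 24 interferon and nucleic acid response genes Ifi27 had the smallest p (1.75 ± 0.69, adjusted p = 0.215), and 0 passed in limma when adjusted over the list alone (3 at an unadjusted p under 0.05, 0 in edgeR or DESeq2, camera adjusted p = 0.794). Markers of cells that could accompany an embryo gave no call in edgeR or DESeq2. Of 7 tested cumulus and granulosa cell markers 0 passed in limma over all genes (1 at an unadjusted p under 0.05), and Tnfaip6 (2.03 ± 0.65, adjusted p = 0.107) rose when adjusted over the list alone (camera adjusted p = 0.525). The median of these markers was 0.60, and 0.44 without Ctrl_LNA 48. It was -0.20 in the lower runs and 1.51 in the upper runs (camera adjusted p = 0.97 and 0.224). Of 8 sperm and spermatid markers 0 passed in limma either way (0 at an unadjusted p under 0.05), and Tekt1 had the smallest p (-1.29 ± 0.64, adjusted p = 0.343, camera adjusted p = 0.895).

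The histone encoded by the injected message is also encoded by H3f3a and H3f3b. H3f3b had 5317 ± 1140 normalised counts in Val_LNA and 5640 ± 3016 in Ctrl_LNA (SD, n = 16 each, adjusted p = 0.999), and H3f3a had 1892 ± 431 and 2550 ± 645 (log2 fold change -0.42 ± 0.14, SE, adjusted p = 0.124). Reads of the injected and the embryo's own message were not separated here.

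Across the 23 lists, 13 were called in camera at its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.375 and 1 list had an unadjusted p under 0.05. Fry called 0 lists in its directional test (lowest adjusted p = 0.349, 3 at an unadjusted p under 0.05) and 0 in its mixed test (lowest adjusted p = 0.0785, 8 at an unadjusted p under 0.05). Without Ctrl_LNA 48 camera called 11 lists. In the lower runs it called 6, and of the 13 the maternal, ribosomal protein, proteasome, DNA replication, G2 and mitosis, pluripotency and translation factor lists were not called there. Over the alternatives other than leaving out each embryo in turn, the calls of the ribosome biogenesis and spliceosome lists were kept in 23 of 23. Those of the 2-cell zygotic, maternal, ribosomal protein and proteasome lists were kept in 22 of 23, and that of the histone list in 19 of 22. The translation factor call was kept in 17, the glycolysis and mitochondrially encoded calls in 16, the DNA replication call in 14, the G2 and mitosis call in 9 and the pluripotency call in 6 of 23. The medians of the ribosomal protein, ribosome biogenesis, spliceosome and proteasome lists stayed negative, and those of the 2-cell zygotic, maternal and histone lists positive, with scaling to the total and with quantile normalization. Median centring moves every list by the same -0.45, so that no negative median can change sign, and left 0.35 for 2-cell zygotic, 0.22 for maternal and 0.41 for histone genes. The median of the DNA replication list was -0.06 with quantile normalization. Quantile normalization also turned the medians of the cholesterol (-0.16), p53 (-0.11), chromatin (-0.047), heat shock (-0.037) and interferon (-0.27) lists negative. The same shift of -0.45 turned every list median between 0 and 0.45 negative, among them those of the DNA replication (-0.35), chromatin (-0.33), mRNA decay (-0.22) and oxidative phosphorylation (-0.21) lists, and so says nothing of a list by itself. Without Ctrl_LNA 48 the medians of the p53 (0.09) and interferon (0.12) lists were -0.15 and -0.24, and those of the heat shock (0.20) and sperm marker (0.22) lists 0.05 and 0.10. The median of the pluripotency list was -0.37 in place of -0.13, and that of the hnRNP list -0.05 in place of -0.02.

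**Figure D3:**
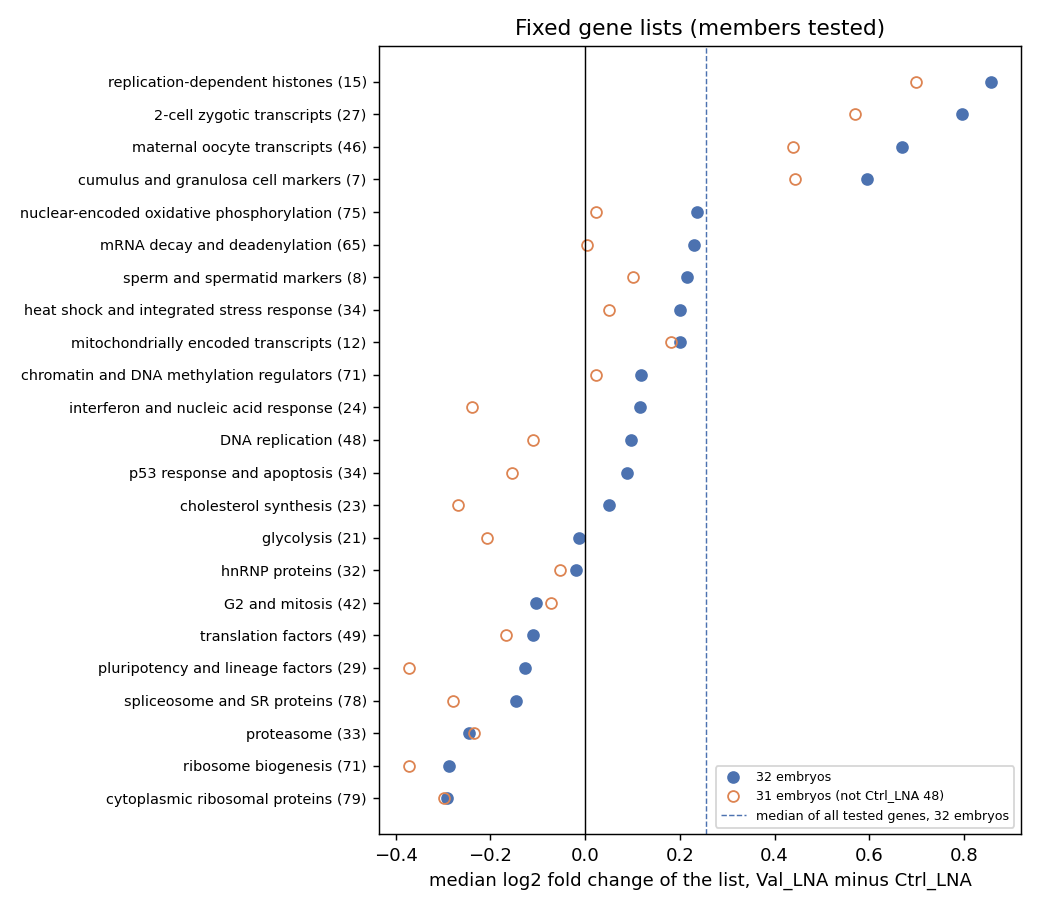
Points give the median log2 fold change, Val_LNA minus Ctrl_LNA, of each fixed list, with the number of tested members beside its name; filled points use 32 embryos and open points leave out Ctrl_LNA 48. The dashed line is the median of all tested genes, 0.26, and the list medians run from -0.29 for cytoplasmic ribosomal proteins to 0.86 for histones.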

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

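No named gene called with all embryos changed direction under any alternative. Sign changes of values past no threshold in either setting are counted as unchanged. The tests without Ctrl_LNA 48, alone or with edgeR, DESeq2, the control axis or the upper runs, were chosen after seeing the data except where each embryo was left out in turn. The cause was not tested for any value here, except that the run settings hold fewer embryos and the filters change the number of genes tested. Against 137 genes higher and 204 lower, DESeq2 called 206 and 338, array weights 353 and 564, and genes detected as a covariate 373 and 363. EdgeR called 29 higher, no filter 87, the filter of 50 in 16 embryos 91, and centring on the median gene 61. Quantile normalization called 385 lower. The lower runs alone called 83 lower, the upper runs 2 higher and 33 lower, and without Ctrl_LNA 48 the upper runs 7 and 124. Without Ctrl_LNA 48 limma called 245 and 409, DESeq2 266 and 402, edgeR 84 higher, and limma with the control axis as a covariate 555 and 602. Leaving out each embryo gave 100 to 245 higher and 176 to 409 lower, with both highest values from Ctrl_LNA 48. Camera called 13 lists, but 7 with quantile normalization, 8 with median centring, 8 with log2 reads as a covariate, 6 in the lower runs, 8 in the upper runs without Ctrl_LNA 48, and 10 to 13 with each embryo left out. No embryo was under 50% of the median depth, so that setting gave no value. For values outside these counts, lists gave 455 unchanged, 65 weaker and 4 stronger tests under other settings and 681 unchanged and 55 weaker with each embryo left out, and named genes 1331, 199 and 15, and 2034, 37 and 9. The G2 and mitosis list had a median of 0.004 in the lower runs (camera adjusted p = 0.892, upwards), and the mitochondrially encoded list -0.25 with median centring, which lowers every list by 0.45 alike (adjusted p = 0.729, downwards). The 2-cell zygotic score difference was 0.38 in the lower runs (exact permutation p = 0.342), 0.50 without Ctrl_LNA 48 (p = 0.057), and 0.50 to 0.84 with each embryo left out. The maternal difference was 1.05 in the upper runs (exact permutation p = 0.042) and 0.34 to 0.65 with each embryo left out, passing without Val_LNA 5 (0.63, p = 0.0497), Ctrl_LNA 34 (0.64, p = 0.0428) or Ctrl_LNA 45 (0.65, p = 0.0339). With each embryo left out the index difference was 0.08 to 0.24, that of log2 reads -0.20 to -0.11, that of genes detected -296 to 565, that of the mitochondrial share 0.246 to 0.444 percentage points and that of the 10 highest genes, tested after seeing the data, 0.658 to 0.873. The last was 0.876 in the lower runs (exact permutation p = 0.088) and 0.677 in the upper runs (exact permutation p = 0.155), or 0.845 without Ctrl_LNA 48 (exact permutation p = 0.0808). The reads difference passed without Val_LNA 20 (-0.20, p = 0.0444), and the mitochondrial one without Val_LNA 14 (0.426, p = 0.0465), Val_LNA 19 (0.433, p = 0.0412) or Ctrl_LNA 31 (0.444, p = 0.0314). Single embryos could not be paired because the groups share no replicate number. With the run of library numbers, lower or upper, as a covariate limma called 145 genes higher and 210 lower. Whether depth limits the calls of genes was not tested. In simulated data with the real depths and spreads, but genes drawn independently, limma recovered 10.6% of genes changed by a fold of 2 that passed the filter.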

Other observations

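The axis, the relations between scores and of the axis with the libraries, the tests without Ctrl_LNA 48, and those by the axis, by library numbers, by abundant genes at 0 and by the index of Ctrl_LNA 48 were chosen after the results were seen. Depth as a covariate and thinned reads were planned, with the bounds for reading them set after the results were seen. Embryos of both groups differed from one another along a common axis. Among 15 control embryos without Ctrl_LNA 48, the main axis of variation held 26.4% of the variance of the tested genes. Its sign was set so that it rose with the maternal list, which holds Wee2 and Spin1. That maternal genes lie at its high and not its low end is therefore not a result. At its high end lay Pou5f1, the pluripotency factor, Wee2, an oocyte kinase, and Spin1, a maternal chromatin reader, with correlations with the axis of 0.975, 0.985 and 0.973 across control embryos and of 0.945, 0.962 and 0.954 across the 16 Val_LNA embryos, which did not define it. At its low end lay Ubxn1 and Cdk2ap1, with -0.973 and -0.956 in controls and -0.908 and -0.851 in Val_LNA. Over the 10 genes at each end, the correlations in Val_LNA ran from 0.867 to 0.983 at the high end and from -0.931 (Pafah1b2) to -0.634 (Hipk3) at the low end. Across genes, which are not independent replicates, the loadings on the main axes of the groups correlated at 0.678. These genes were picked as the ends of the axis, so their control values are not independent of it. Those named are only a part of the 10 at each end. A difference between the groups along the axis was within the spread between embryos (means of 16.4 ± 66.5 in Val_LNA and 0.0 ± 94.9 in Ctrl_LNA, SD, n = 16 and 15, permutation p = 0.577). The difference was -14.4 in the lower runs (exact permutation p = 0.716, n = 8 and 8) and 53.2 in the upper runs (exact permutation p = 0.193, n = 8 and 7).

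The axis also followed measures of the libraries, in 10 relations, each adjusted over the 10. With the share of counts in the 10 highest genes r was 0.76 in Val_LNA (permutation p = 0.00087, adjusted p = 0.0034, rho = 0.685, permutation p = 0.0045) and 0.824 in Ctrl_LNA (permutation p = 0.00025, adjusted p = 0.0025, rho = 0.839, permutation p = 0.00018). Without the 2 embryos farthest along the axis these were 0.729 and 0.769, and within runs 0.855 and 0.627 in Val_LNA and 0.819 and 0.771 in Ctrl_LNA. With genes detected r was 0.554 in Val_LNA (permutation p = 0.025, adjusted p = 0.041, rho = 0.518, permutation p = 0.043) and 0.735 in Ctrl_LNA (permutation p = 0.0027, adjusted p = 0.0066, rho = 0.757, permutation p = 0.0018). Without the 2 farthest embryos these were 0.811 and 0.686, and within runs 0.873 and -0.022 in Val_LNA and 0.541 and 0.815 in Ctrl_LNA. With genes detected after thinning of the reads r was 0.581 (permutation p = 0.019, adjusted p = 0.037, rho = 0.541, permutation p = 0.033) and 0.78 (permutation p = 0.001, adjusted p = 0.0034, rho = 0.793, permutation p = 0.00077), without the 2 farthest 0.862 and 0.759, and within runs 0.947 and -0.101 in Val_LNA and 0.596 and 0.876 in Ctrl_LNA. With log2 reads r was -0.25 (permutation p = 0.35, adjusted p = 0.5, rho = -0.2, permutation p = 0.46) and -0.189 (permutation p = 0.5, adjusted p = 0.62, rho = -0.057, permutation p = 0.84), without the 2 farthest -0.425 and -0.507, and within runs -0.431 and 0.198 in Val_LNA and -0.115 and -0.211 in Ctrl_LNA. With the mitochondrial share r was 0.031 (permutation p = 0.91, adjusted p = 0.92, rho = -0.047, permutation p = 0.86) and 0.03 (permutation p = 0.92, adjusted p = 0.92, rho = -0.007, permutation p = 0.98), without the 2 farthest 0.357 and 0.025, and within runs 0.258 and -0.539 in Val_LNA and 0.263 and -0.533 in Ctrl_LNA. The axis is thus not told apart here from differences between libraries in genes detected and in the weight of the highest genes.

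Scores of the fixed lists also varied together, in 6 relations between scores, each adjusted over the 6. Whether the scores follow the control axis was not tested, so these relations are not told apart from that axis. Val_LNA 14, the highest of its group on the axis (135), had its highest maternal score (1.67) and lowest ribosome biogenesis score (-1.45). Val_LNA 7, the lowest on the axis (-88.0), had the highest ribosome biogenesis score (0.89). Ctrl_LNA 32, the highest control on the axis (159), had a ribosome biogenesis score of -1.02 but not the highest maternal score (0.26). Across the 16 Val_LNA embryos the maternal score and the ribosome biogenesis score ran in opposite directions (r = -0.954, rho = -0.953, both permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 6e-05). Across the 15 control embryos r was -0.792 (permutation p = 0.00041, adjusted p = 0.0012) and rho -0.804 (permutation p = 0.0005). Without the 2 embryos farthest from the median maternal score r was -0.944 and -0.786. Within the runs r was -0.961 and -0.991 in Val_LNA and -0.677 and -0.932 in Ctrl_LNA. The zygotic and maternal scores rose together, with r = 0.594 in Val_LNA (permutation p = 0.015, rho = 0.706, permutation p = 0.0028) and r = 0.667 in Ctrl_LNA (permutation p = 0.0066, rho = 0.668, permutation p = 0.008). Without the 2 farthest embryos these were 0.624 and 0.697, and within runs 0.787 and 0.348 in Val_LNA and 0.531 and 0.704 in Ctrl_LNA. The zygotic and ribosome biogenesis scores had r = -0.682 in Val_LNA (permutation p = 0.0032, rho = -0.721, permutation p = 0.0023) and r = -0.767 in Ctrl_LNA (permutation p = 0.00068, rho = -0.711, permutation p = 0.0039). Without the 2 farthest embryos these were -0.684 and -0.626, and within runs -0.82 and -0.372 in Val_LNA and -0.765 and -0.642 in Ctrl_LNA.

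For the 341 genes called between the groups, 1 of 100 splits of the 32 embryos, the real one, gave as many. The highest other gave 2, so chance is argued against as the source if the embryos are independent. Splits of single embryos cannot exclude a chance difference between matings, injection days or runs of library numbers. Without Ctrl_LNA 48, 2 of 100 splits gave as many as the real 654 (highest other 1523), and that other split was the one of the 100 most correlated with the control axis (absolute r = 0.508, against 0.104 for the real split). Depth and the control axis are argued against as whole causes. The called genes kept a median of 0.979 of their fold change with log2 reads as a covariate and 0.988 with the axis. With log2 reads as a covariate limma called fewer genes, 104 higher and 164 lower. Of these, 95 and 159 were among the calls without it. Whether the higher share of counts in the 10 highest genes in Val_LNA plays a part was not tested. A difference in preparation cannot be told apart from the treatment, because 0 runs of library numbers hold both groups. Between the runs within either group limma called 0 genes. At an unadjusted p under 0.05 there were 913 in Val_LNA and 1422 in Ctrl_LNA, or 1682 in Ctrl_LNA without Ctrl_LNA 48. These comparisons stay within a group, so they cannot show a preparation difference between the groups. An effect of the antisense oligonucleotide thus stays a hypothesis beside a difference in preparation.

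The shift of the lists stands on weaker ground than the single genes. The real split called 13 lists in camera, and 1 of 100 splits of the 32 embryos, the real one, gave as many, with 12 in the highest other and a median of 5. Without Ctrl_LNA 48 the real split called 11, reached by 3 of 100 splits including the real one, with 15 in the highest other. By this count the real split lay under 0.05 in both, but 100 splits of single embryos are few, and chance is not excluded. Most arbitrary splits also called lists, as would be found if members of a list vary together. With an estimated correlation 0 lists passed in camera (1 at an unadjusted p under 0.05).

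For the few genes detected in Ctrl_LNA 48, shallow sequencing is argued against, because with all embryos thinned to 2592925 reads the lowest other embryo still had 2.54 times as many genes (16118 against 6350). Its zygotic minus maternal index was 0.11, within the -1.14 to 1.24 of the other controls, but both scores were low (-3.60 and -3.71). An index of 2 scores lowered alike cannot tell whether the zygotic genome was active, so an inactive zygotic genome stays open. Loss of transcripts at random before amplification may account for the few genes detected. Of 6921 genes with a mean of at least 100 in the other controls, 31.9% were at 0 in Ctrl_LNA 48. In another control embryo the share was at most 0.939%. The design gives no group that would explain a single control embryo, and no other biological explanation was tested.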
